A study of Caenorhabditis elegans with 12 samples.

How the data were processed

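Gonads were dissected with needles from adult F3 nematodes kept at 20 °C whose P0 ancestors had been exposed to water, DMSO or BPA. Per the labels' protocols, RNA from these gonads was made into cDNA with a SMART-Seq kit for very small inputs, amplified, converted to libraries with a Nextera XT kit and sequenced as single-end reads of 50 bp. The labels give 12 libraries, 4 for each exposure, and group and sample number were taken from their titles. The labels do not say that samples of a group are separate cultures, so p-values measure only the spread between these samples, which may be technical. They do not say what equal sample numbers share either, so the numbers were not used as a block.

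The authors deposited 1 table of transcript values for each library. Per the file headers, the authors gave RPKM (reads scaled to transcript length and library size) in 11 tables and FPKM in the table of BPA 1, the same quantity for single-end reads. Per the submitters' processing notes, HISAT and StringTie were used with the genome build ce10. Their versions, the annotation and any filter are not given in the sources used here. Every table lists the same 49201 transcripts. The transcript models group them into 37450 loci, of which 3605 hold more than 1 gene name, so that reads of neighbouring or overlapping genes can be divided differently from library to library. No step that keeps the strand is named in the labels, so antisense genes are uncertain, as are near-identical copies such as the core histone and major sperm protein genes.

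Values of transcripts with the same gene name were summed to 40961 genes, and 279 transcripts without a name were left out (0.88% to 2.67% of the summed value of a library). Genes with at least 1 RPKM in at least 4 of the 12 libraries were tested, 7570 in all. A value of 0 can be a failed estimate here: 10 of 66 tested ribosomal protein genes are listed at 0 in some library, and so are 103 of the 2603 tested genes that exceed 50 RPKM in another, 76 of them at loci with several gene names. Such genes are given as listed at 0, library by library. The oocyte regulator puf-5, for example, is at 498 RPKM in BPA 1 and listed at 0 in BPA 3. Chromosomes were taken by name from the Ensembl release 115 annotation, which uses another build, so no coordinates are given. Of the gene names 40458 matched it, and 98.1% of the tested genes had a chromosome.

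The files hold no counts. In genes with 1 transcript, the most frequent product of value and transcript length within each library was taken as the step that 1 read makes. This gave an estimated depth of 14.6, 26.2, 14 and 18.4 M reads (M, 1e6) for water 1 to 4, 17.1, 16.9, 33.1 and 19 M for DMSO 1 to 4, and 20.9, 18.8, 19.9 and 18.2 M for BPA 1 to 4. Too few values were whole reads within 0.1 for a test on counts. No 2 libraries were copies: at most 0.91% of genes had identical values in a pair.

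Differences were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with all 12 libraries in 1 fit, a trend of variance with intensity, two-sided tests and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. A fold change on this scale understates the change of low genes. All adjusted p-values of genes are from limma. Of 38 gene lists fixed before the data were examined, 36 had at least 5 tested members and were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the members of a list move, on balance, in 1 direction. The lists of major sperm protein genes and of mitochondrially encoded genes had 0 tested members. The groups, comparisons, lists, alternatives and the rule for named genes were all chosen before the data were examined, save where the text says otherwise. The rule names up to 10 called genes in each direction whose groups do not overlap, or, with fewer than 5, also the 5 with the smallest unadjusted p, 14 fixed genes (jmjd-2, jmjd-3.1, jmjd-3.2, jmjd-3.3, utx-1, met-2, set-25, mes-2, let-858, hrde-1, cep-1, ced-3, egl-1 and vit-2), and for each list up to 4 called members or the 2 with the highest mean. Single values of locus sums were compared by exact permutation tests in R 4.3.3. Values were summed per gene and figures drawn in Python 3.11.15.

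The procedure was tested on simulated data with the comparison of BPA with DMSO (10 runs with 7570 genes, 200 of them changed). All changed genes had a mean of at least 10 RPKM, and genes varied independently. False calls made up 5.6% of calls, and a list of 40 such independent genes shifted by 0.5 was found in 20 of 20 runs. In the real lists the estimated correlation between members ranged from -0.04 (neuron markers) to 0.98 (vitellogenins), with 0.22 for oocyte and egg genes. How often a list of correlated genes is found at the adjusted threshold was not tested, so these runs do not give the power of the real list test. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 10 RPKM, upper-quartile scaling, quantile normalization, the sample number as a block, only the compared groups in the fit, library weights, and each library left out in turn. Further alternatives, chosen after the data were seen, left out water 1 and 3, summed values per locus, kept only genes alone at their locus, and took odd or even sample number as a term or each kind alone.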

Results

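RNA sequencing measured gene expression in gonads dissected from adult Caenorhabditis elegans of the F3 generation. The P0 ancestors of these animals had spent 48 h in water, in the solvent dimethyl sulfoxide (DMSO, 0.1%) or in 100 µM bisphenol A (BPA), a building block of plastics dissolved in DMSO. Each ancestral exposure was represented by 4 libraries, 12 in all, named here by group and sample number. The depth estimated from the smallest values of each library was 14 to 33.1 M reads (M, 1e6). It is a rough figure, since 32.1% to 37% of the low values came out as whole reads within 0.1 read. The yolk receptor gene rme-2 stood at 1819 ± 140 RPKM in BPA, 1780 ± 367 RPKM in DMSO and 1632 ± 806 RPKM in water (mean ± SD, n = 4), and the germ granule helicase gene glh-1 at 829 ± 156, 842 ± 35.9 and 836 ± 485 RPKM. Of the protein-coding genes, 23% on chromosome V to 55.6% on chromosome III were expressed highly enough to be tested on the autosomes, and 30.4% on the X chromosome. The median level of the tested X-linked genes was 3.39 RPKM, and the medians of the 5 autosomes lay between 15.2 and 27.01 RPKM.

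The comparison of BPA with DMSO asks whether the ancestral exposure to BPA, beyond its solvent, left a difference in the F3 gonad. Only 2 of 7570 genes passed the test (limma, Benjamini-Hochberg adjusted p under 0.05), and both were lower in BPA. The first was arx-6, which encodes a subunit of the Arp2/3 complex that nucleates branched actin filaments. It was listed at 24.1, 26.5, 14.8 and 20.0 RPKM in the DMSO libraries, at 0.94 RPKM in BPA 1 and at 0 in the other BPA libraries. Every water library listed arx-6 at 0 as well, and the log2 difference between BPA and water was 0.24. For this gene DMSO, and not BPA, thus stood apart from water. The second was ZK418.5, listed at 41.9, 29.96, 15.35 and 18.25 RPKM in DMSO and at 0, 0, 1.66 and 1.40 RPKM in BPA. On the log2(RPKM + 1) scale arx-6 fell by 4.21 (SE 0.26, adjusted p = 1.82e-05) and ZK418.5 fell by 4.00 (SE 0.40, adjusted p = 0.00188). The sizes of these changes depend on the pseudocount of 1.

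Both genes lie on chromosome III, and in the deposited transcript models each shares a merged locus with a neighbour. The locus of arx-6 also holds C35D10.18 and C35D10.1, of which C35D10.1 stood at 29.5 to 46.5 RPKM in DMSO and 44.8 to 48.4 RPKM in BPA. The locus of ZK418.5 also holds lin-37, which encodes a component of the DREAM repressor complex. It stood at 28.9 to 36.6 RPKM in DMSO and at 45.2 to 54.9 RPKM in BPA. Summed over its locus, the signal around arx-6 was 46.4 ± 1.56 RPKM in BPA and 57.5 ± 10.7 RPKM in DMSO (mean ± SD, n = 4), a log2 difference of -0.29 (exact permutation test, two-sided, p = 0.0286). The locus of ZK418.5 summed to 49.04 ± 4.16 and 59.6 ± 9.14 RPKM, a log2 difference of -0.27 (exact permutation test, two-sided, p = 0.0857, n = 4). With 4 against 4 libraries this permutation test can give no p under 0.0286. It was not adjusted, and each sum includes the gene whose call led to the test. With values summed per locus, neither locus passed the test across all loci. Among genes alone at their locus, which leaves out both of these genes, limma called 0 in each of the 3 comparisons.

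**Figure D1:**
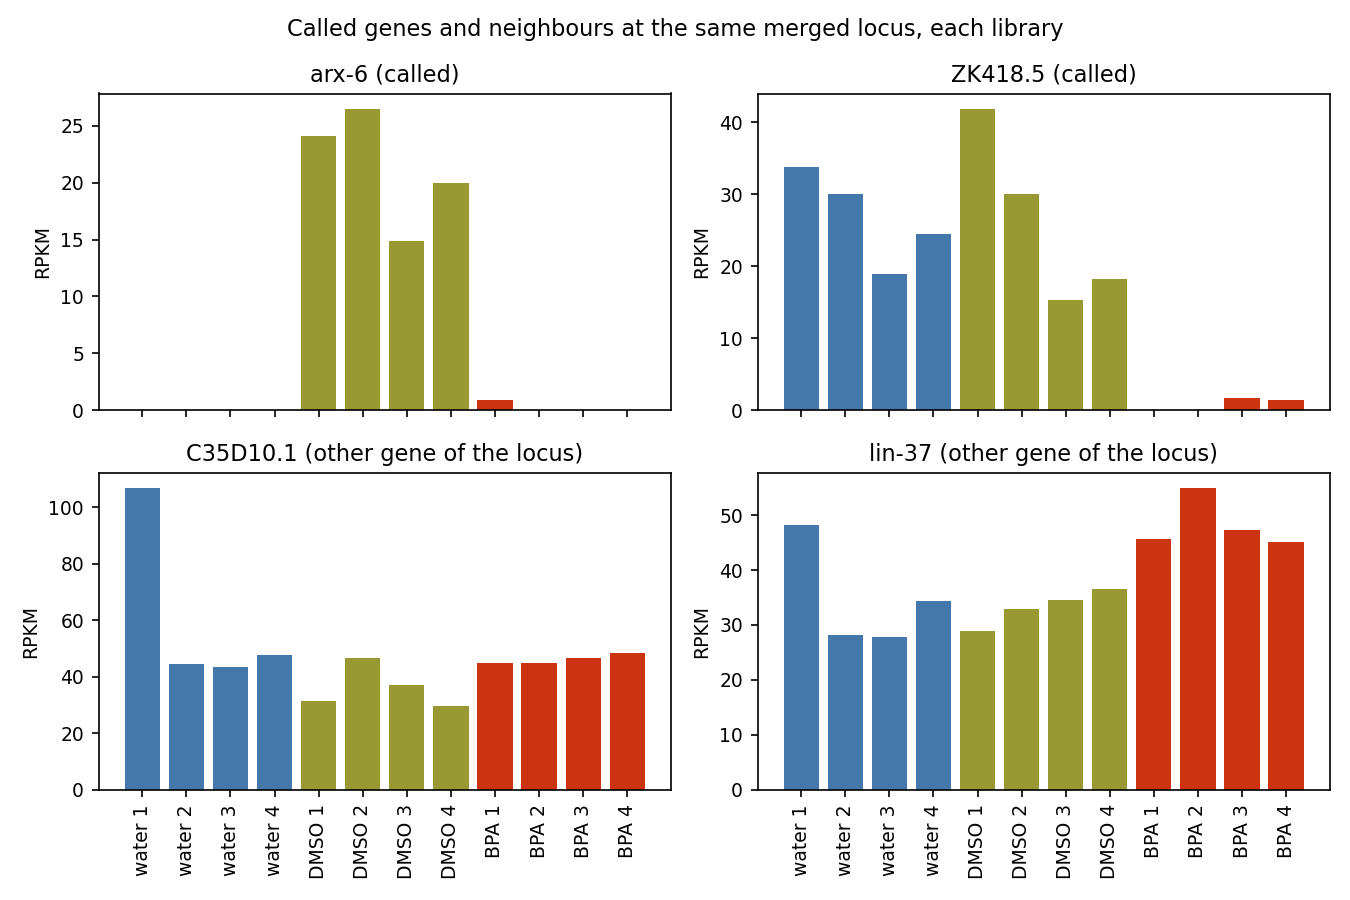
RPKM of arx-6 and ZK418.5 (upper panels) and of C35D10.1 and lin-37, the neighbours at the same merged loci (lower panels), with 1 bar for each of the 12 libraries in blue (water), olive (DMSO) and red (BPA). arx-6 reads 14.8 to 26.5 RPKM in DMSO and at most 0.94 RPKM in the other 8 libraries, and ZK418.5 at most 1.66 RPKM in BPA.

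No gene passed in the upward direction. The genes with the smallest unadjusted p among those higher in BPA were csnk-1, K03B4.1, F43G6.10, Y50D4A.5 and Y39B6A.42. The casein kinase I gene csnk-1 stood at 13.5 ± 3.19 RPKM in BPA and 2.59 ± 1.101 RPKM in DMSO (n = 4 each; log2 difference 2.04, SE 0.40, adjusted p = 0.746), but it shares a locus with ced-12, and the locus as a whole differed by 0.04. Without water 1, whose spread enters the fit, csnk-1 passed (adjusted p = 0.0404), and with array weights it passed as well (adjusted p = 0.0273). K03B4.1 stood at 50.4 ± 5.84 and 22.7 ± 7.28 RPKM (adjusted p = 1). Y39B6A.42 was listed at 14.8 to 20.5 RPKM in BPA and at 16.6, 0.79, 0.33 and 0 RPKM in DMSO, and it passed without DMSO 1 (adjusted p = 9.67e-05). Over the alternatives its adjusted p reached up to 1. On the lower side, the corresponding genes were pas-7, R05D7.8, M05D6.2, adr-2 and 21ur-2599, with log2 differences between -4.38 and -1.52 (adjusted p = 1). M05D6.2 shares a locus with zyg-9, fars-3 and F22B5.10. That locus summed to 118.4 ± 17.04 RPKM in BPA and 183.8 ± 12.19 RPKM in DMSO, a log2 difference of -0.64 (exact permutation test, two-sided, p = 0.0286, n = 4). This is the smallest p the test can give here, unadjusted. The sum includes M05D6.2 itself, so it is no separate evidence. The proteasome subunit gene pas-7 stood at 5.40 ± 3.84 RPKM in BPA and 21.25 ± 12.4 RPKM in DMSO, and the RNA-editing adenosine deaminase gene adr-2 at 0 to 2.21 RPKM in BPA and 2.52 to 16.45 RPKM in DMSO.

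The histone demethylase genes in the title of the study showed no difference larger than the spread between libraries. jmjd-2 stood at 44.8 ± 7.11 RPKM in BPA and 43.6 ± 4.83 RPKM in DMSO (log2 difference 0.03, SE 0.15, n = 4). utx-1 stood at 4.71 ± 2.71 and 3.85 ± 2.19 RPKM (0.22, SE 0.41). jmjd-3.1 stood at 1.23 ± 0.40 and 1.64 ± 0.54 RPKM (-0.24, SE 0.21), and jmjd-3.2 and jmjd-3.3 were too low to be tested, at no more than 0.29 RPKM in any library. utx-1 parted by sample number in BPA and DMSO but not in water, with 7.07 and 7.02 RPKM in BPA 1 and 3 and 2.63 and 2.11 RPKM in BPA 2 and 4, with 5.28 and 6.16 RPKM in DMSO 1 and 3 and 1.93 and 2.04 RPKM in DMSO 2 and 4, and with 2.90 and 5.57 RPKM in water 1 and 3 and 3.98 and 2.99 RPKM in water 2 and 4. The histone methyltransferase gene met-2 stood at 57.0 ± 10.9 RPKM in BPA and 40.8 ± 3.55 RPKM in DMSO (0.45, SE 0.21, adjusted p = 1). set-25, the Polycomb-type methyltransferase gene mes-2 and let-858 differed by 0.06, 0.06 and 0.03. The nuclear Argonaute gene hrde-1 differed by 0.10, the p53 homologue cep-1 by 0.16 and the caspase gene ced-3 by 0.16. The cell death activator egl-1 differed by 0.51 (SE 0.62) and the yolk protein gene vit-2 by -0.31 (SE 1.06). Each tested gene of this set had an adjusted p of 1.

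At an unadjusted p under 0.05, 66 genes differed between BPA and DMSO, where chance would give 378.5, and 82 genes (1.08%) had groups that did not overlap, where chance gives 2.86%. The unadjusted count was 99 with odd or even sample number as a term and 172 with array weights. A count below chance thus does not show that the groups are alike. The median 95% confidence interval of a log2 difference reached 0.58 to either side, and 0.46 (1.38-fold) for the 4262 genes with a mean of at least 10 RPKM. In simulated data for this comparison with 7570 genes, the test recovered 61.4% of 2-fold, 81.2% of 2.83-fold, 89% of 4-fold and 95.6% of 16-fold changes. All changed genes there had a mean of at least 10 RPKM, and genes varied independently. Recovery among lower genes, or where only a few genes change, was not tested. With fewer changed genes the adjusted threshold is stricter, so these shares do not hold for isolated changes. The count of called genes was 4 in sample numbers 1 and 3 alone (C35D10.5, the mitochondrial ribosome gene mrps-12 and the endosome gene rab-5 higher and R05D3.2 lower, named after their values were seen), 12 in sample numbers 2 and 4 alone and 2 with odd or even sample number as a term. Settings that ended the call of ZK418.5 included a pseudocount of 0.1 (log2 difference -5.92, adjusted p = 0.111), only the 2 groups in the fit (log2 difference unchanged, adjusted p = 0.0529), sample numbers 1 and 3 alone (-4.02, adjusted p = 0.78) and 2 and 4 alone (-3.98, adjusted p = 0.115), within a range over the alternatives from 0.000699 to 0.78. That of arx-6 ended in sample numbers 1 and 3 alone (-3.84, adjusted p = 0.241, range from 7.09e-06 to 0.241), and arx-6 was not among the genes with a mean of at least 10 RPKM.

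No list of germline genes differed between BPA and DMSO past the threshold. None of 36 fixed lists passed the test (limma's camera, smallest adjusted p = 0.505), 2 lists had an unadjusted p under 0.05, and limma's fry gave 0 lists as well. The median log2 difference was 0.05 for oocyte and egg genes (27 of 40 members above 0), 0.03 for meiosis, pairing, synapsis and recombination (36 of 57), 0.07 for germline stem cell and translational regulators (24 of 32) and 0.04 for the germ granule and small RNA pathway (47 of 65). Sperm and spermatid genes had a median of -0.19 (6 of 17 above 0), and the 30 major sperm protein genes were too low to be tested. DMSO 1 stood apart in the sperm list, with 3.38 (mean log2) against 1.72 to 2.15 in the other DMSO libraries, and without it the median was -0.07. Among oocyte genes, perm-2 stood at 2151 ± 727 RPKM in BPA and 2122 ± 508 RPKM in DMSO (n = 4). The synaptonemal complex gene syp-4 stood at 253 ± 21.4 and 259 ± 33.8 RPKM, the RNA helicase gene cgh-1 at 529 ± 63.2 and 504 ± 39.3 RPKM, and the Argonaute gene wago-1 at 684 ± 131 and 673 ± 117 RPKM. Cell cycle and chromosome segregation genes had a median of 0.04 (46 of 69 above 0), and apoptosis, engulfment and DNA damage checkpoint genes 0.03 (24 of 41).

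No list of chromatin genes passed between BPA and DMSO. The medians were 0.07 for histone demethylases (mean 0.21, 9 of 12 above 0), 0.02 for histone methyltransferases and repressive chromatin (27 of 46), 0.07 for X chromosome dosage compensation (mean 0.17, 10 of 11) and -0.06 for core histone genes (5 of 12). The demethylase gene jmjd-1.2 stood at 90.4 ± 3.83 RPKM in BPA and 86.1 ± 7.65 RPKM in DMSO, the chromodomain gene cec-3 at 496 ± 28.99 and 494 ± 46.2 RPKM, and the condensin gene mix-1 at 166 ± 10.7 and 160 ± 16.99 RPKM (n = 4). By chromosome the medians lay between 0.01 and 0.02 for the autosomes and at 0.05 for the X chromosome (520 of 830 above 0).

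Genes of stress and detoxification did not pass either. Heat shock, unfolded protein and oxidative stress genes had a median of 0.10 (25 of 34 above 0), with the chaperone gene daf-21 at 2159 ± 168 RPKM in BPA and 1999 ± 189 RPKM in DMSO (n = 4). The medians were -0.03 for cytochrome P450 genes (4 of 11), -0.14 for UDP-glucuronosyltransferase genes (0 of 7), 0.11 for glutathione S-transferase genes (8 of 12) and 0.00 for ABC transporters (9 of 19). C-type lectin and lysozyme genes had a median of -0.07 (9 of 26), F-box A, MATH and BATH genes -0.01 (45 of 96), nuclear hormone receptors -0.01 (29 of 64) and lipid metabolism 0.02 (22 of 38). Ribosomal proteins had a median of 0.09 (50 of 66), the proteasome 0.05 (24 of 30) and the nuclear-encoded respiratory chain and ATP synthase 0.02 (27 of 43). Adjusted over the list alone, 1 proteasome gene was lower (pas-7, adjusted p = 0.047), which was not among the calls over all genes, and 2 genes of chromosome III were lower (arx-6 and ZK418.5), which were.

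No list of markers of other tissues passed between BPA and DMSO. The vitellogenins, yolk protein genes of the intestine, had a median log2 difference of -0.59 with 0 of 5 members above 0. Their summed level was 917 RPKM in DMSO 3 and 17.4 to 61.9 RPKM in the other DMSO libraries, against 18.9 to 109 RPKM in BPA. The medians were -0.12 for intestine markers (6 of 15 above 0), 0.12 for muscle markers (16 of 23), 0.11 for hypodermis and cuticle collagens (16 of 29), -0.09 for hypodermis markers other than collagens (3 of 9), 0.03 for neuron markers (5 of 9) and 0.06 for somatic gonad, sheath and basement membrane genes (15 of 22). The median, the mean and the direction of the test differed in sign for apoptosis, cell cycle, core histone, collagen, other hypodermis, neuron, lipid metabolism, proteasome and respiratory chain genes and for chromosomes I, II and IV. The count of lists past the threshold was 2, 4 and 3 without DMSO 1, 2 and 3, and 1, 6 and 1 without BPA 2, 3 and 4. It was 3 with array weights, 3 in sample numbers 1 and 3 alone and 5 in sample numbers 2 and 4 alone.

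**Figure D2:**
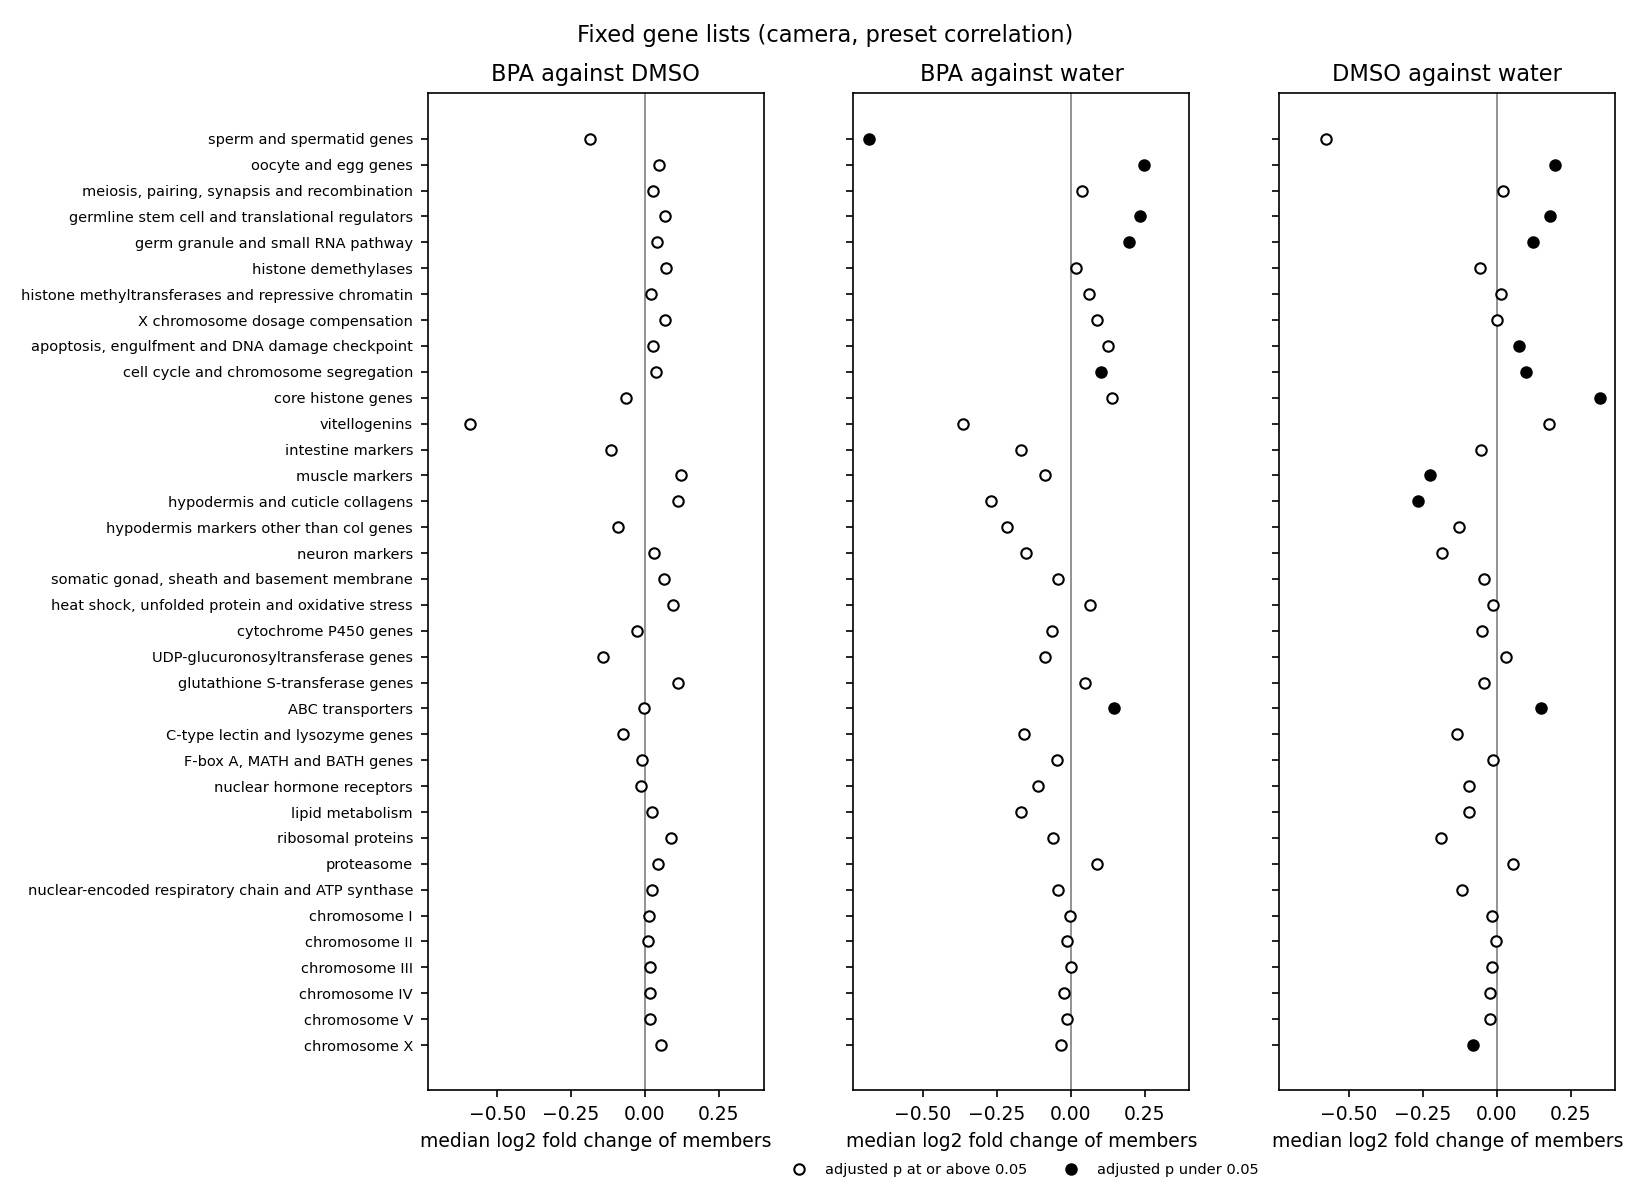
Median log2 fold change of the members of each of the 36 tested gene lists (horizontal axes) in the 3 comparisons, with filled points for lists at an adjusted p under 0.05 (camera, preset correlation) and open points for the others. No list passed between BPA and DMSO, 6 passed between BPA and water and 10 between DMSO and water.

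Against water, the second control, BPA differed in 1 gene. ZK418.5 was listed at 33.8, 30, 18.9 and 24.45 RPKM in water, and it fell by 4.10 in BPA (SE 0.40, adjusted p = 0.00293, n = 4). Its locus differed by -0.29 (exact permutation test, two-sided, p = 0.0857). Settings that ended the call included a pseudocount of 0.1 (log2 difference -6.03, adjusted p = 0.0942), sample numbers 1 and 3 alone (-4.01, adjusted p = 0.572) and 2 and 4 alone (-4.18, adjusted p = 0.0746), within a range from 0.00171 to 0.572. With the pseudocount of 0.1 Y102A5C.36 was called higher in its place (5.66, adjusted p = 0.0452, up to 1 over the alternatives). No gene was called higher (limma, with 205 genes at an unadjusted p under 0.05). The genes with the smallest unadjusted p on that side were Y39B6A.42, Y102A5C.36, csnk-1, F43G6.10 and his-35. Y39B6A.42 was at no more than 0.55 RPKM in water, and csnk-1 stood at 3.52 ± 3.19 RPKM (log2 difference 1.88, SE 0.40, adjusted p = 0.887). On the lower side were F14D2.14, B0035.21, F15E6.4, R05D7.8 and T07E3.3. Of these, F14D2.14 was listed at 0 in all 4 BPA libraries and at 4.12 to 15.4 RPKM in water. T07E3.3 stood at 24.4 ± 5.85 RPKM in BPA and 39.2 ± 9.58 RPKM in water (adjusted p = 0.987). met-2 differed by 0.47 (SE 0.21), set-25 by 0.28 (SE 0.13) and jmjd-2 by 0.13 (SE 0.15), all with an adjusted p of 0.987. The demethylase gene utx-1 differed by 0.13 (SE 0.41). The groups did not overlap for 153 genes (2.02%, chance 2.86%). With only the compared groups in the fit the count was 3, since Y39B6A.42 (adjusted p = 0.000508, up to 0.999 over the alternatives) and F14D2.14 (adjusted p = 0.023, up to 1) joined. It was 2 without water 1 and with array weights (csnk-1 joined), without DMSO 1 (Y39B6A.42 joined) and without DMSO 4 (F14D2.14 joined), 4 in sample numbers 1 and 3 alone and 16 in sample numbers 2 and 4 alone.

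Between BPA and water 5 lists were higher and 1 was lower past the threshold with the preset correlation, and none passed with an estimated correlation. Oocyte and egg genes had a median of 0.25 (32 of 40 above 0, adjusted p = 0.000167), germline stem cell and translational regulators 0.23 (26 of 32, adjusted p = 0.000167) and the germ granule and small RNA pathway 0.20 (49 of 65, adjusted p = 0.000167). Each of these had adjusted p = 0.592 with an estimated correlation. Cell cycle and chromosome segregation genes had a median of 0.10 (51 of 69, adjusted p = 0.00138) and ABC transporters 0.15 (16 of 19, adjusted p = 0.0398), with adjusted p = 0.592 and adjusted p = 0.842 with an estimated correlation. Sperm and spermatid genes had a median of -0.68, with 12 of 17 below 0 (adjusted p = 0.015), and adjusted p = 0.592 with an estimated correlation. The germline list of meiosis genes did not pass (median 0.04, adjusted p = 0.267, and adjusted p = 0.762 with an estimated correlation). No single member passed: rme-2 differed by 0.32 (SE 0.36), cgh-1 by 0.70 (SE 0.47) and glh-1 by 0.24 (SE 0.44). Adjusted over the list alone, 1 core histone gene was higher (his-35, adjusted p = 0.012), which was not among the calls over all genes, and 1 gene of chromosome III was lower (ZK418.5). The germline lists moved with water 1, where germ granule genes averaged 4.85 (mean log2) against 5.30 to 5.37 in the other water libraries. Without water 1 the count of lists fell from 6 to 1. The sperm list moved with water 3, where its genes summed to 989 RPKM against 141 to 158 RPKM in the other water libraries. The adjusted p of the sperm list was 0.505 without water 3, 0.0924 without water 2 and 0.0525 without BPA 3, within a range over the alternatives from 5.91e-05 (without water 1) to 0.77 (fry). Without a filter neither the sperm list (adjusted p = 0.731) nor ABC transporters passed, and the median of ABC transporters turned to -0.03, while apoptosis (adjusted p = 0.00165) and core histone genes (adjusted p = 0.00372) did. ABC transporters did not pass with only the compared groups (adjusted p = 0.0635) or with array weights (adjusted p = 0.408). The cell cycle list did not pass after quantile normalization (adjusted p = 0.0636). The sperm list and the cell cycle list did not pass with a mean of at least 10 RPKM either. The median, mean and test differed in sign for histone demethylases, heat shock, ribosomal protein and proteasome genes and for chromosomes I, II, III and V, none of which passed.

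The comparison of DMSO with water measures the solvent by itself. Its 1 call was arx-6, listed at 14.8 to 26.5 RPKM in DMSO and at 0 in all 4 water libraries (adjusted p = 9.80e-06). The signal of its locus was 57.5 ± 10.7 RPKM in DMSO and 60.6 ± 30.8 RPKM in water, a log2 difference of 0.02 (exact permutation test, two-sided, p = 0.971, n = 4). The call ended in sample numbers 1 and 3 alone (log2 difference 4.32, adjusted p = 0.136, range from 3.16e-06 to 0.136), and arx-6 was not among the genes with a mean of at least 10 RPKM. No gene was called lower (limma, with 129 genes at an unadjusted p under 0.05). Next among the higher genes were adr-2, the mitochondrial kinase gene pink-1, Y65B4BL.3, pas-7 and Y102A5C.36. adr-2 stood at 9.21 ± 5.86 RPKM in DMSO and was listed at 0, 0, 1.14 and 0 RPKM in water (adjusted p = 0.573). pink-1 was at 5.68 to 15.4 RPKM in DMSO and listed at 0 in all 4 water libraries, and pas-7 stood at 21.25 ± 12.4 and 4.90 ± 1.66 RPKM (adjusted p = 0.999). Among the lower genes were B0035.21, F15E6.3, hsp-70, K05C4.4 and F14D2.14. The heat-inducible chaperone gene hsp-70 stood at 2.82 ± 0.71 RPKM in DMSO and 19.1 ± 18.6 RPKM in water (log2 difference -2.02, SE 0.52, adjusted p = 0.999), with 46.6 RPKM in water 4. The fixed genes jmjd-2, utx-1 and met-2 differed by 0.10, -0.09 and 0.02. The groups did not overlap for 67 genes (0.89%, chance 2.86%). With only the compared groups in the fit the count was 3, since pink-1 (adjusted p = 0.00263) and Y65B4BL.3 (adjusted p = 0.000172) joined. Over the alternatives the adjusted p of both reached up to 1, and Y65B4BL.3 passed also in sample numbers 2 and 4 alone (adjusted p = 0.00426). The count was 2 without DMSO 4 (F14D2.14 joined), 5 in sample numbers 1 and 3 alone and 7 in sample numbers 2 and 4 alone.

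Between DMSO and water 7 lists were higher and 3 were lower past the threshold with the preset correlation, and none passed with an estimated correlation. Of the higher lists, oocyte and egg genes had a median of 0.20 (33 of 40 above 0, adjusted p = 0.000823), germline stem cell and translational regulators 0.18 (23 of 32, adjusted p = 0.00274), cell cycle and chromosome segregation 0.10 (47 of 69, adjusted p = 0.00274), germ granule and small RNA pathway 0.12 (44 of 65, adjusted p = 0.00569) and ABC transporters 0.15 (17 of 19, adjusted p = 0.00569). The first 4 had adjusted p = 0.685 with an estimated correlation, and ABC transporters had adjusted p = 0.705 with an estimated correlation. Core histone genes had a median of 0.35 (9 of 12, adjusted p = 0.0483) and apoptosis, engulfment and DNA damage checkpoint genes 0.08 (27 of 41, adjusted p = 0.0483), both with adjusted p = 0.685 with an estimated correlation. The 3 lower lists were muscle markers with a median of -0.23 (20 of 23 below 0, adjusted p = 0.0215), hypodermis and cuticle collagens with -0.27 (22 of 29, adjusted p = 0.0483) and the X chromosome with -0.08 (542 of 830, adjusted p = 0.0471). Collagens had adjusted p = 0.685 with an estimated correlation, and muscle markers and the X chromosome had adjusted p = 0.989 with an estimated correlation. The troponin C gene pat-10 differed by -0.64 (SE 1.05) and the collagen gene col-178 by -1.71 (SE 1.35). Adjusted over the list alone, 1 proteasome gene was higher (pas-7, adjusted p = 0.0487), which was not among the calls over all genes, and 1 gene of chromosome III (arx-6). The count of lists was 1 without water 1, 6 without water 3 and 5 without DMSO 4, and without water 1 none of the 10 passed. The medians then were 0.05 for oocyte genes, 0.06 for stem cell regulators and 0.03 for the germ granule, but still -0.26 for collagens (adjusted p = 0.0675), -0.19 for muscle markers (adjusted p = 0.0671) and 0.29 for core histone genes (adjusted p = 0.184). Core histone genes averaged 2.45 (mean log2) in DMSO 1 against 1.24 to 1.82 in the other DMSO libraries and 1.12 to 1.54 in water. With a pseudocount of 0.1 apoptosis genes and collagens did not pass (adjusted p = 0.0632 for both), nor did they with only the compared groups (adjusted p = 0.0531 and 0.0508). With a pseudocount of 5 core histone genes (adjusted p = 0.0638) and the X chromosome (adjusted p = 0.0501) did not pass, and the sperm list did (median -0.30, adjusted p = 0.0484). With a mean of at least 10 RPKM germ granule genes, apoptosis genes, muscle markers and the X chromosome did not pass. With array weights only oocyte and core histone genes of the 10 did, and the sperm list joined (adjusted p = 0.0275). After quantile normalization the X chromosome (median -0.01, adjusted p = 0.83), collagens, core histone and apoptosis genes did not pass, and after upper-quartile scaling the X chromosome, collagens and apoptosis genes did not. Without a filter muscle markers, collagens, ABC transporters (median -0.01) and the X chromosome did not pass. The median, mean and test differed in sign for X chromosome dosage compensation, intestine markers and the autosomes, none of which passed. The same water libraries differed in sperm and other tissue markers: muscle markers summed to 778 RPKM in water 3 and to 254 to 456 RPKM in the other water libraries, and collagens to 646 and 135 to 212 RPKM.

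ZK418.5 was the 1 gene that differed between BPA and both controls. The 2 comparisons share the BPA libraries, and in 100 simulations with unchanged groups the overlap averaged 0.01 genes and reached 1 in the highest. Independent lists of 2 and 1 lower genes among 7570 would share 0.000264. Both values assume genes and libraries that vary independently, which the real ones do not, so they may make an overlap of 1 look rarer than it is. Of 100 groupings of the real libraries, 21 gave an overlap of at least 1 (highest of the others 2). That test was chosen after the results were seen. In each of 6 divisions of the BPA libraries between the comparisons, the overlap was 1. Settings that gave an overlap of 0 included a pseudocount of 0.1, only the compared groups in the fit and values summed per locus. The overlap was 2 without water 1, 2 without DMSO 1, 2 with array weights, 2 in sample numbers 1 and 3 alone and 8 in sample numbers 2 and 4 alone.

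Libraries also differed in ways that the exposure groups do not describe. Water 1 correlated least with the others (mean r 0.88 across genes, against 0.914 to 0.937), with the eukaryotic elongation factor gene eef-1G at 4084 RPKM against at least 13268 RPKM elsewhere. Water 3 carried transcripts of sperm: major sperm protein genes summed to 259 RPKM against at most 14 RPKM in any other library, and the sperm phosphatase gene gsp-3 was at 55.7 RPKM, against 6.36 RPKM in DMSO 1 and at most 1.52 RPKM elsewhere. X-linked genes averaged 2.47 to 2.78 (mean log2) in sample numbers 1 and 3 of all 3 groups and 1.98 to 2.19 in sample numbers 2 and 4. The same sample numbers parted for C44B7.5, at 350 to 1215 RPKM and 9.16 to 57.3 RPKM, and for pat-10, at 67.6 to 325 RPKM and 12.4 to 35.2 RPKM, genes singled out after their values were seen. Each group holds 2 libraries of each kind, so that the exposure groups are balanced over them.

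**Figure D3:**
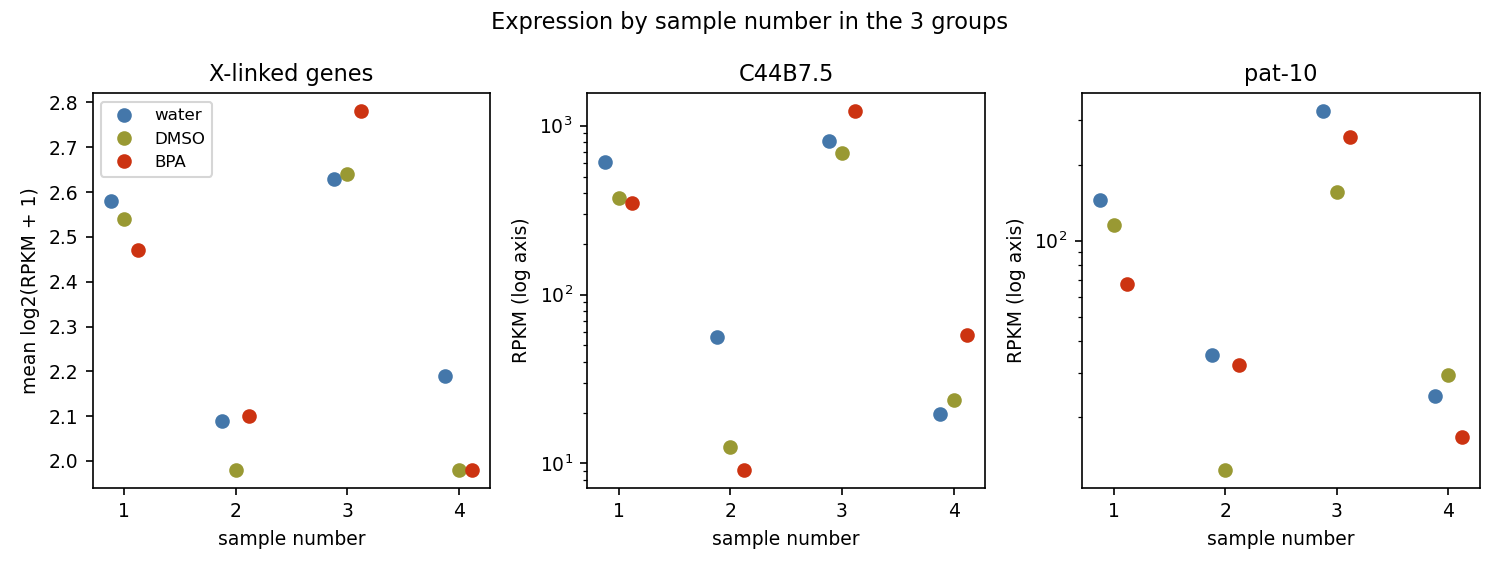
Mean log2(RPKM + 1) of the 830 tested X-linked genes, and RPKM of C44B7.5 and pat-10 on log axes, against the sample number, with 1 point per library in blue (water), olive (DMSO) and red (BPA). In all 3 panels the samples numbered 1 and 3 lie above those numbered 2 and 4.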

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

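The counts over other splits of the libraries, also those balanced over sample numbers, the sums over loci and the counts of lists without water 1 or without water 3 are tests chosen after the results were seen.

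Among 155 groups of 4 values, 11 held a library far from the other 3, where chance marks about 1 in 20 groups, or 7.8. Germ granule and small RNA pathway genes averaged 4.85 (mean log2) in water 1 against 5.30 to 5.37 in the other water libraries, 5.16 in DMSO 2 against 5.36 to 5.39, and 5.48 in BPA 1 against 5.37 to 5.38. Germline stem cell and translational regulators averaged 5.90 in DMSO 2 against 6.10 to 6.13, and oocyte and egg genes 7.04 in BPA 4 against 7.33 to 7.38. The log2 value of hrde-1 was 6.11 in water 1 against 7.15 to 7.32, that of mes-2 was 5.64 in BPA 3 against 5.47 to 5.49, and that of arx-6 was 0.96 in BPA 1 with the other BPA libraries listed at 0. Lipid metabolism genes averaged 3.63 in water 3 against 2.95 to 3.04, and glutathione S-transferase genes 2.53 in BPA 3 against 2.11 to 2.12. The estimated depth of DMSO 3 was 33.1 M reads (M, 1e6) against 16.9 to 19 M.

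arx-6 and ZK418.5 were the genes called between the exposure groups, and over all splits chance could not be excluded for the counts: 4 of 35 splits of the BPA and DMSO libraries gave as many genes as the real 2 (highest of the others 505), 9 of 35 as many as the 1 of BPA against water (highest 1), 11 of 35 as many as the 1 of DMSO against water (highest 3), and 21 of 100 as many as the 1 against both controls (highest 2). The split with 505 genes parts sample numbers 1 and 3 from 2 and 4, which points to a structure of the samples (counts within these 4 and 12), and of the 18 splits with 2 libraries of either kind on both sides 1, the real one, gave 2 genes between BPA and DMSO (highest of the others 1, with too few splits for a share under 0.05), 6 gave as many as the 1 of BPA against water (highest 1) and 9 as many as the 1 of DMSO against water (highest 3). A candidate explanation for both genes is reads shared between genes of 1 merged locus. On average a neighbour stood higher in BPA than in DMSO at both loci. C35D10.1 was at 46.2 ± 1.77 against 36.1 ± 7.58 RPKM, and lin-37 at 48.3 ± 4.5 against 33.3 ± 3.29 RPKM (n = 4). The locus of arx-6 changed by -0.29 where the gene fell by 4.21, and that of ZK418.5 by -0.27 where the gene fell by 4.00. These sums cannot tell shared reads from a real loss. The neighbours supply much of each sum, so that a loss of the gene alone would also change it by less than the gene. Genes at shared loci made up 23 of the 35 genes with an unadjusted p under 0.05 and more than a 2-fold difference between BPA and DMSO (65.7%), against 17.3% of the tested genes (Fisher's exact test over genes, which are not independent, p = 2.48e-10). A real switch between the neighbours after ancestral exposure stays open and was not tested.

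The gene lists past the threshold against water were not beyond chance either: 26 of 35 splits gave as many lists as the 6 of BPA against water (highest of the others 13), and 10 of 35 as many as the 10 of DMSO against water (highest 15). Among the 18 splits balanced over sample numbers, 14 gave as many as the 6 (highest of the others 13). As many as the 10 came from 4 of 18 (highest of the others 13). For BPA against DMSO the splits decide nothing, since each of the 35 gives at least the real 0 lists (highest 14). Without water 1, the library apart from the rest, 1 list passed in each comparison with water, the sperm list, so that the higher oocyte, germ granule and stem cell lists may come from a lower level in water 1, but not so the collagens, muscle markers and core histone genes of DMSO against water, whose medians stayed at -0.26, -0.19 and 0.29 without their calls. DMSO 1 stood apart in core histone genes, with 2.45 (mean log2) against 1.24 to 1.82 in the other DMSO libraries and 1.12 to 1.54 in water. Sperm carried in 1 library, water 3, is a candidate explanation for the sperm list of BPA against water, whose adjusted p was 0.505 without that library. An effect of the solvent or of BPA on these lists was not excluded by these tests, and it remains open.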

How the results depend on the processing

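The counts without water 1 and 3, for sample numbers 1 and 3 alone and 2 and 4 alone, for genes alone at their locus, for values summed per locus, and for all alternatives of the difference by sample number are tests chosen after the data were seen. Counts are of called genes (BPA against DMSO 2, BPA against water 1, DMSO against water 1, both controls 1) and of lists (0, 6 and 10). No named gene reversed past the threshold. With a pseudocount of 5, without a filter and with upper-quartile scaling all of these counts stayed within 1.5 times. A pseudocount of 0.1 left 1 gene between BPA and DMSO and 0 against both controls, and the 1 gene between BPA and water was then Y102A5C.36, higher, and not ZK418.5. The filter on a mean of at least 10 RPKM left 1 gene between BPA and DMSO, 0 between DMSO and water, and 6 lists between DMSO and water (fewer genes were tested). Quantile normalization left 6 lists between DMSO and water. With only the 2 groups compared there were 1, 3 and 3 genes and 0 against both controls. Array weights gave 2 genes between BPA and water, 2 against both controls, 3 lists between BPA and DMSO and 4 between DMSO and water. Without water 1 and 3 there were 7 genes and 0 lists for BPA against water, and 7 genes and 1 list for DMSO against water. Sample numbers 1 and 3 alone gave 4, 4 and 5 genes, 2 against both controls and 3 lists between BPA and DMSO. Sample numbers 2 and 4 alone gave 12, 16 and 7 genes, 8 against both controls, 5 lists between BPA and DMSO and 6 between DMSO and water. Among genes alone at their locus there were 0, 0 and 0 calls by limma and 0 against both controls, since the called genes share loci. Values summed per locus gave 1 call between BPA and DMSO (the locus of C36A4.11, higher in BPA, named after its values were seen), 0 between BPA and water and 0 against both controls, and the 1 call between DMSO and water was the same locus, lower in DMSO, and not arx-6. An estimated correlation left 0 and 0 lists against water, and fry 0 and 0. Leaving out each library in turn gave 2 to 3, 1 to 2 and 1 to 2 genes, 1 to 2 against both controls, and 0 to 6, 1 to 9 and 1 to 13 lists. Where no reason is given, the cause was not tested.

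With the sample number as a replicate block there were 1 gene between BPA and DMSO, 0 between BPA and water and 0 against both controls, and no other count moved by more than 1.5 times. The log2 changes of ZK418.5 were the same, with adjusted p = 0.0683 against DMSO and adjusted p = 0.114 against water. Residuals of samples with the same number correlated by -0.067 to 0.34, over 0.1 in 5 of 12 pairs, and 6 of 12 libraries correlated best with their own number, a hint from the data and not from the design.

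The 695 genes that differed between sample numbers 1 and 3 and sample numbers 2 and 4 were 390 without a filter, 55 with a mean of at least 10 RPKM, 86 after quantile normalization, 1292 with array weights, 395 to 988 without single libraries, and 1, 15 and 13 within water, DMSO and BPA alone (fewer samples). Of 1765 values of named genes under alternatives, 1663 kept their direction and side of the threshold, 11 lost a call, 18 gained one, and 73 changed sign without ever passing. No other deposited unit was run, since each table holds 1 unit. The median 95% confidence interval reached 0.58 to either side over all genes and 0.46 over those with a mean of at least 10 RPKM, and how much of this is depth was not tested.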

Other observations

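The comparison of sample numbers 1 and 3 with sample numbers 2 and 4, and all its tests, were chosen after the pattern was seen in the data.

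In every exposure group, genes of the X chromosome were higher in samples numbered 1 and 3 than in those numbered 2 and 4, by a median of 0.45 in water, 0.62 in DMSO and 0.68 in BPA. The medians of the tested genes not on the X chromosome were 0.15, -0.01 and 0.04. With exposure group in the fit, 695 of 7570 genes differed by sample number (limma, 674 higher and 21 lower in numbers 1 and 3), and 316 of the 830 X-linked genes were higher (38.1%) against 337 of 6593 autosomal genes (5.11%; Fisher's exact test over genes, which are not independent, p = 6.48e-145). The median log2 difference was 0.60 for X-linked genes, with 763 of 830 above 0, and 0.04 for autosomal genes. Examples, named after their values were seen, were sex-1, an X-linked nuclear receptor gene, at 7.09 ± 1.19 and 2.67 ± 0.45 RPKM (n = 6 each, log2 difference 1.14, SE 0.14, adjusted p = 0.00442), the clathrin adaptor gene dpy-23 at 7.24 ± 0.91 and 3.102 ± 0.42 RPKM, and the cyclophilin gene cyn-8 at 37.8 ± 6.18 and 16.35 ± 2.70 RPKM. The demethylase gene utx-1 stood at 5.67 ± 1.54 and 2.61 ± 0.78 RPKM (log2 difference 0.87, adjusted p = 0.0282), whereas met-2 differed by -0.03.

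Some autosomal genes moved further. C44B7.5 differed by 4.64 (676 ± 320 and 29.8 ± 21.6 RPKM, n = 6, adjusted p = 0.0041) and the troponin C gene pat-10 by 2.68 (177.5 ± 95.3 and 25.06 ± 9.04 RPKM, adjusted p = 0.00468). Of the lists, 4 rose in numbers 1 and 3: the X chromosome (adjusted p = 9.43e-38), nuclear hormone receptors (median 0.48, 57 of 64 above 0), muscle markers (0.77, 23 of 23) and somatic gonad, sheath and basement membrane (0.29, 17 of 22). Ribosomal proteins (-0.26, 7 of 66 above 0), germ granule genes (-0.11), meiosis genes (-0.06) and chromosome III (0.01, above 0 although its test was downward) fell relative to other genes. The X chromosome alone kept its call, adjusted p = 0.037 with an estimated correlation. The others lost it in that test: nuclear hormone receptors had adjusted p = 0.287 with an estimated correlation, muscle, meiosis and chromosome III 0.322, ribosomal proteins 0.56, and somatic gonad and germ granule 0.713. By fry, which asks whether a list moves and not whether it moves more than other genes, 15 of 36 lists passed, among them nuclear hormone receptors (adjusted p = 0.000526), muscle markers (0.00321), neuron markers (0.0101), somatic gonad (0.0271), X chromosome dosage compensation (0.0286), histone demethylases (0.034) and 5 of the 6 chromosomes, but none of the 4 lower lists.

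Of 100 splits with 2 libraries of each group on either side, drawn from 108, 1 gave as many genes, the real one with 695. The highest of the others gave 246. The real split was picked because its pattern had been seen, so that its rank does not exclude chance. Within water, DMSO and BPA alone 1, 15 and 13 genes differed, of which 0, 2 and 0 were X-linked genes higher in numbers 1 and 3. Low values or depth are argued against, because autosomal genes matched on mean value reached a median of at most 0.23 in 1000 draws against 0.60 for the X chromosome, and the estimated depth was 19.9 ± 7.0 and 19.6 ± 3.3 M reads (M, 1e6) (exact permutation test, p = 0.926, n = 6). A larger share of somatic tissue in the samples numbered 1 and 3 may account for it, since X-linked genes stood low in these gonads. The median of the tested genes was 3.39 RPKM on the X chromosome and 15.2 to 27.01 RPKM on the autosomes. Of 6 lists of other tissues, 2 were higher past the threshold and 4 were not, which leaves this open. The 2 were muscle (adjusted p = 0.322 with an estimated correlation) and somatic gonad (adjusted p = 0.713 with an estimated correlation). Neuron markers passed besides these by fry alone, and the vitellogenins, not counted here, did not pass (median 1.69, adjusted p = 0.0964). Of those 4 lists, intestine markers had a median of 0.55 (13 of 15 above 0) and collagens 0.35 (21 of 29). Neuron markers had a median of 0.09 (7 of 9) and other hypodermis markers -0.06 (4 of 9). No other biological explanation was tested, as the labels give the sample number no meaning. The count without single libraries was 452 without DMSO 3, 456 without DMSO 4, 443 without BPA 2, 407 without BPA 3 and 395 without BPA 4, and after quantile normalization it was 86, with an X-linked median of 0.31.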
